A study of Mus musculus with 4 samples.

How the data were processed

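Total RNA from p53-null mouse embryonic fibroblasts, 5 days after retroviral transduction, was labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels. Group and replicate number were taken from the sample labels: 2 arrays for OSK and 2 for OSK+Glis1. The authors deposited 1 scanner table per array with intensity values written by Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal, an intensity, is background-subtracted and spatially detrended by the scanner software and not normalized between arrays, per the file headers. The raw median spot intensity, the local background intensity and the quality flags come from the same deposited tables. The authors also deposited a table of log2 values for the whole series whose processing is not given in the sources used here. Set against the scanner values, it equals the log2 of the mean processed signal of a probe minus the array's median, with 99.7% to 99.8% of probes within 0.01 of 1 constant per array, and it is not centred per gene. The medians of its 4 columns were 3.1e-06, -0.00016, 0.000216 and 4.8e-05 for OSK replicates 1 and 2 and OSK+Glis1 replicates 1 and 2. Scale, centring and direction of that table are thus settled, while the tool that made it is not known.

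Each array held 43379 non-control spots of 41174 probes. The processed signal was put on the log2 scale and the array's 75th percentile of it was subtracted. These percentiles were 951 and 669 intensity units for OSK replicates 1 and 2, and 845 and 949 for OSK+Glis1 replicates 1 and 2. Control spots and spots flagged as outliers were left out, spots of 1 probe were averaged, and 71 probes without an unflagged spot on every array were dropped. A probe entered the test when it was well above background on both arrays of at least 1 group. The scanner tables used here pair probes with accessions, and gene symbols were taken from a RefSeq gene table of assembly GRCm38.p6, matched without versions. The array annotation names build mm9, so no coordinates are given. In all, 26901 probes matched a symbol. A gene was represented by its probe with the highest mean over the 4 arrays, which gave 19171 genes, 13507 with a symbol and 5664 under their accession or probe name. Of 659 changed genes with more than 1 probe, all probes moved the same way for 652.

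Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fit had 2 residual and 2.82 prior degrees of freedom. Signal that was not well above background on either array of a group gives only a bound. The fold is then "at least" the bright group's mean against the mean, over the dim group's arrays, of the higher of the lowest well-above-background signal and the probe's own signal. This applied to 212 genes that rose and 251 that fell. Their p-values are for the fitted difference, which uses the dim group's signals as they stand, and the bound itself was not tested. Gene lists, 27 in number, were tested with camera (preset correlation 0.01) and adjusted over the lists. None of the 5 lists past the threshold kept its call with an estimated correlation. That form of the test rests on the 2 residual degrees of freedom, so few lists could pass it. For the question genes the estimated correlation (-0.03) lay below the preset, yet the unadjusted camera p went from 6.1e-07 to 0.0346. A call lost there therefore says little about the list. The adjusted p of 0.964 given below is 1 tied value, shared by lists whose unadjusted camera p differ (0.19 for fibroblast matrix, 0.274 for squamous epithelium). The directional fry test passed for 2 lists, the question genes (adjusted p = 0.0132) and the glycolysis and hypoxia genes (adjusted p = 9.7e-04), and its mixed test for 21. Fry does not compare a list with other genes. In 5 lists the median, the mean and the direction of the test differ in sign: mesenchymal transition, trophoblast and placenta, Myc-responsive ribosome biogenesis, oocyte and early embryo, and housekeeping controls. Beside the lists in the comparison, lists of trophoblast, oocyte, leukocyte, endothelial, muscle, neural, adipocyte with cartilage and bone, and Y-linked or Xist genes were fixed.

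Groups, tests, lists, alternatives and the rule for named genes were written before the data were examined. The rule takes the 4 transduced factors and the question genes, the 12 largest rises and 12 largest falls among named genes past the threshold without overlap between groups, and up to 4 members of each list, those past the threshold first. It gave 128 genes, 102 of them past the threshold, and 1 of these is not reported here by name. The steps were tested on simulated data with the real gene means and the fitted spread, in 20 simulations of 19171 genes with 200 changed. At 2-fold 0.716% of changed genes were recovered, at 4-fold 59.3%, at 8-fold 87.3% and at 16-fold 93.5%. Of all calls 5.06% were false, and 0 had the wrong sign. The simulated share of changed genes was far below the 14.2% called in the data, and recovery depends on that share. These recovery rates therefore do not give the power of the comparison itself. Errors were drawn independently from limma's own fitted spread, so a false share near the threshold was built in.

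Alternatives covered background correction, normalization (quantile, median centring, the deposited log2 values), the filter on dim probes, the choice among a gene's probes, the replicate number as a block, the eBayes settings, thresholds, the set tests and leaving out each array. The normexp alternative (offset 50) was planned on the mean spot signal. The scanner tables used here hold the median spot signal, which was used in its place. After seeing its result, a version was added in which local backgrounds that the scanner marked as non-uniform take the array's median background. All 4 arrays share 1 slide and 1 scan, so slide or scan as a block was not run. Figures were drawn with matplotlib 3.10.9.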

Results

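Gene expression was measured in mouse embryonic fibroblasts (MEFs) that lacked p53, 5 days after retroviral delivery of reprogramming factors. One group received OSK, the labels' name for a factor set that in this field stands for Oct4 (gene Pou5f1), Sox2 and Klf4. The other group received OSK together with Glis1, a zinc finger transcription factor of the Gli-similar family. Each group had 2 one-colour microarrays, 1 RNA sample per array, and all 4 arrays lay on 1 slide. The labels describe the cells of the OSK arrays as embryonic fibroblasts and those of the OSK+Glis1 arrays as induced pluripotent cells derived from them. All labels give day 5, while the names of the deposited scanner tables carry a number that differs between replicates 1 and 2 in both groups, whose meaning is not given in the sources used here. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Between 59.9% and 65.2% of the spots on an array were well above background, and 0 spots were saturated. The number of arrays limits the precision.

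The question was which genes differ when Glis1 is added to OSK during the first days of reprogramming. The 2 groups differed widely: 2726 of 19171 genes tested (14.2%) passed an adjusted p of 0.05 in limma, with 1160 higher and 1566 lower in the arrays labelled OSK+Glis1. The genes that rose included the forkhead factor Foxa2, the Wnt ligands Wnt3, Wnt6, Wnt8a and Wnt10a, and the Myc family members Mycn and Mycl. Myc itself fell, and so did 17 of 26 measured genes of the fibroblast extracellular matrix and 13 of 26 of squamous epithelium (9 and 4 without OSK replicate 1). The transduced factors gave no check of the labels, because the Glis1 probe was not higher in the arrays labelled OSK+Glis1. Its signal lay at -3.30 ± 0.05 (SD, n = 2) in OSK and -3.51 ± 0.32 (SD, n = 2) in OSK+Glis1, in log2 units relative to each array's 75th percentile. Where this probe lies on the transcript, and whether it reads the retroviral copy, is not given in the sources used here. Directions below therefore refer to the groups as labelled.

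Across genes, the arrays of a group resembled each other more than arrays of different groups. The correlation was 0.987 between the OSK arrays and 0.989 between the OSK+Glis1 arrays, against 0.935 to 0.945 between groups. Genes are not independent replicates, so these values describe the arrays only. The SD of the log2 differences across genes was 0.51 and 0.48 within the groups, and 1.14 and 1.06 between same-numbered arrays of different groups.

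Among the changed genes, 2396 differed at least 2-fold, with 999 higher and 1397 lower. By size alone, 3124 genes differed at least 2-fold with both arrays of one group above both arrays of the other, 1307 of them higher and 1817 lower in OSK+Glis1. Groups without overlap, at any size, were found for 59.9% of genes, and chance gives 33.3%. An unadjusted p under 0.05 was reached by 5605 genes. The split between higher and lower calls depended on the centring: 42.6% of the changed genes were higher as scaled here, 53% with each array centred on its median and 54.4% in the authors' deposited log2 values. The median difference of all genes was 0.05 as scaled here, 0.19 with median centring and 0.21 in the deposited values. Leaving out 1 array lowered the count to 1241 without OSK replicate 1, 1219 without OSK replicate 2 and 1592 without OSK+Glis1 replicate 1. Without a filter on dim probes 1504 genes passed. A planned background correction (normexp on spot and local background signals) left 0 genes in limma, with 1411 at an unadjusted p under 0.05. On OSK replicate 2, 6 spots carried local backgrounds far above their signal, and the fitted background mean of that array was -662.8, against -5.76 to -20.4 on the other arrays. With the scanner's flagged local backgrounds replaced by the array median, an alternative added after seeing that result, 2849 genes passed.

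Of the genes of the delivered factors, only Pou5f1 passed the test. Its probe was 11.2-fold higher in OSK+Glis1 (log2 difference 3.49 ± 0.55 SE, limma adjusted p = 0.0194), with 1 OSK array well above background. On OSK replicate 2 its signal (-5.725) lay below the lowest well-above-background signal (-5.56) and enters the fold as it stands. Delivered copies and the cells' own transcripts were not measured apart, so the difference does not show that more of the factor was delivered. The Pou5f1 call was lost without OSK replicate 1, without OSK replicate 2 and without the filter on dim probes. Klf4 was at 3.09 ± 0.12 in OSK and 3.22 ± 0.54 in OSK+Glis1 (SD, n = 2), with a limma adjusted p of 0.812. Sox2 was not well above background in OSK and had an adjusted p of 0.408 in limma, and Glis1 had 0.598. As a list, the 4 transduced factors had a median difference of 0.63 and a camera adjusted p of 0.575. Adjusted over the list alone, 1 was higher and 0 lower, as over all genes. The count higher was 0 without either OSK array in turn and 2 without OSK+Glis1 replicate 1.

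**Figure D1:**
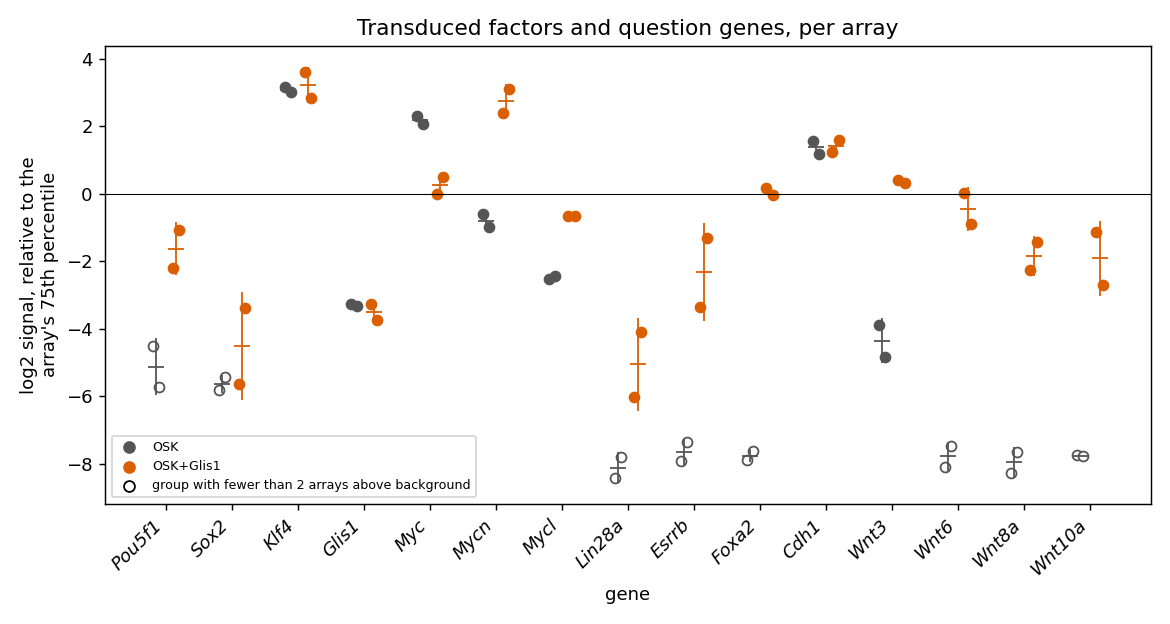
Log2 signal relative to each array's 75th percentile (y axis) for the transduced factors and the question genes (x axis). Points are single arrays of OSK (grey) or OSK+Glis1 (orange), bars are the mean ± SD of 2 arrays, and open points mark a group with fewer than 2 arrays well above background. Foxa2, Wnt6 and Wnt8a lie near the bottom in OSK and between -2.27 and 0.17 in OSK+Glis1, while the Glis1 points of both groups lie between -3.73 and -3.26.

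A first list held genes that the study of Glis1 in reprogramming is known for, such as Myc family genes, Lin28a, Foxa2, Esrrb and Wnt ligands, and it is therefore not independent evidence of a direction. Of its 11 measured members, 9 were higher and 1 was lower. Adjusted over the list alone, the counts were also 9 and 1. Foxa2, a pioneer factor of endoderm, was at least 61.4-fold higher (limma adjusted p = 0.00189), since it was not well above background in OSK. Likewise Wnt6 was at least 43.4-fold, Wnt8a at least 16.4-fold and Wnt10a at least 15.6-fold higher, with adjusted p of 0.00231, 0.00253 and 0.00497 in limma. Wnt3 rose 26.3-fold (log2 difference 4.72 ± 0.34 SE), Mycn 11.7-fold (3.54 ± 0.30 SE) and Mycl 3.57-fold (1.83 ± 0.16 SE). Myc fell 3.84-fold (log2 difference -1.94 ± 0.24 SE, limma adjusted p = 0.0098), and all 3 of its probes fell. The orphan receptor Esrrb was at least 11.8-fold higher (limma adjusted p = 0.012), and the RNA-binding protein gene Lin28a at least 1.77-fold (limma adjusted p = 0.0489). For genes with bounds these p-values rest on fitted differences that use signals not well above background. The fitted log2 difference of Lin28a was 3.05 and its bound 0.83, which was not tested. The adhesion gene Cdh1 was at 1.38 ± 0.28 in OSK and 1.41 ± 0.23 in OSK+Glis1 (SD, n = 2), with a limma adjusted p of 0.944. No probe was matched to Nanog, and no Lin28b probe was well above background on both arrays of a group. The list passed camera's test upwards (adjusted p = 8.2e-06), its adjusted p was 0.934 with an estimated correlation, and it was 0.116 over genes well above background on all 4 arrays. The calls of Myc, Esrrb, Wnt10a and Lin28a were each lost without OSK replicate 1 and without OSK replicate 2. Lin28a also lost its call without the filter and under normexp with flagged backgrounds replaced.

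Of 30 measured pluripotency genes, 7 were higher and 0 lower (10 and 0 adjusted over the list alone), Esrrb and Lin28a from the list above among them. The count higher was 3 without OSK replicate 1 and 2 without OSK replicate 2, and 2 members were lower without OSK+Glis1 replicate 2. The list had a median difference of 0.08 and a camera adjusted p of 0.208. That p was 0.0431 without a filter and 0.015 without OSK+Glis1 replicate 1. The de novo DNA methyltransferase gene Dnmt3b rose 7.33-fold (log2 difference 2.87 ± 0.24 SE, limma adjusted p = 0.00422) and the zinc finger gene Sall1 rose 3.87-fold (1.95 ± 0.23 SE). Dppa3 was at least 2.53-fold higher (limma adjusted p = 0.0137), a call lost without either OSK array in turn and under normexp with flagged backgrounds replaced.

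Of 26 measured fibroblast matrix genes, 17 were lower and 1 was higher (18 and 2 adjusted over the list alone), and the median difference was -1.74, or -1.66 with dim genes at their bounds. The list passed camera downwards (adjusted p = 4.1e-08), and its adjusted p was 0.964 with an estimated correlation. The count lower was 9 without OSK replicate 1 and 10 without OSK replicate 2. Lumican (Lum), a collagen-binding proteoglycan, fell 4.49-fold (log2 difference -2.17 ± 0.21 SE), the collagen gene Col6a2 3.47-fold (-1.80 ± 0.16 SE) and elastin (Eln) 7.34-fold (-2.88 ± 0.23 SE). Dermatopontin (Dpt) was at least 2.75-fold lower, a call lost under normexp with flagged backgrounds replaced. The exception was the growth factor receptor gene Pdgfra, which rose 6.18-fold (log2 difference 2.63 ± 0.55 SE, limma adjusted p = 0.0416) and was named after its value was seen. No member was higher without either OSK array in turn, without OSK+Glis1 replicate 1 or without a filter, and 2 were higher without OSK+Glis1 replicate 2.

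Of 26 measured genes of squamous epithelium, 13 were lower and 2 higher (14 and 5 adjusted over the list alone), with a median of -1.31, or -1.26 with bounds. The camera adjusted p was 0.0175, and 0.964 with an estimated correlation. Transglutaminase 1 (Tgm1), which cross-links the cornified envelope, fell 22.4-fold (log2 difference -4.49 ± 0.25 SE), the kallikrein Klk10 17.3-fold (-4.11 ± 0.26 SE) and the basal keratin Krt14 8.65-fold (-3.11 ± 0.28 SE), while the keratin Krt15 rose 8.50-fold (3.09 ± 0.18 SE). Without OSK replicate 1 the camera adjusted p was 0.0657, with 4 members lower and 1 higher. Only 1 was higher without OSK replicate 2 or without OSK+Glis1 replicate 1 as well. It was 0.121 over genes well above background on all 4 arrays and 0.0675 without a filter.

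Of 22 measured inflammatory genes, 8 were lower and 3 higher (11 and 4 adjusted over the list alone), and the median was -1.15. Camera gave an adjusted p of 0.0283, and 0.964 with an estimated correlation. Cyclooxygenase 2 (Ptgs2) fell 13.4-fold (log2 difference -3.75 ± 0.20 SE), the interleukin 1 receptor antagonist Il1rn 8.92-fold (-3.16 ± 0.18 SE) and the chemokine Cxcl5 6.80-fold (-2.77 ± 0.17 SE). The cytokine Il11 rose 81.2-fold (6.34 ± 0.26 SE, limma adjusted p = 0.00225). Without OSK replicate 1, 5 were lower and 1 higher, and without OSK replicate 2, 5 were lower. The call was lost without OSK replicate 1 (0.2), without OSK+Glis1 replicate 2 (0.234) and without a filter (0.0737).

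Of 29 measured cell cycle genes, 2 were higher and 0 lower (also 2 and 0 adjusted over the list alone), the median difference was 0.35 and 26 differences were positive. Camera's adjusted p was 0.00172, but 0.964 with an estimated correlation and 0.0657 without OSK replicate 1. Only 1 gene was higher without OSK replicate 1 or without either OSK+Glis1 array in turn. The higher genes were the cyclin Ccne1, 3.40-fold (log2 difference 1.77 ± 0.21 SE), and the topoisomerase Top2a, 2.20-fold (1.14 ± 0.19 SE), whose call was lost without any 1 of the 4 arrays and without a filter.

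**Figure D2:**
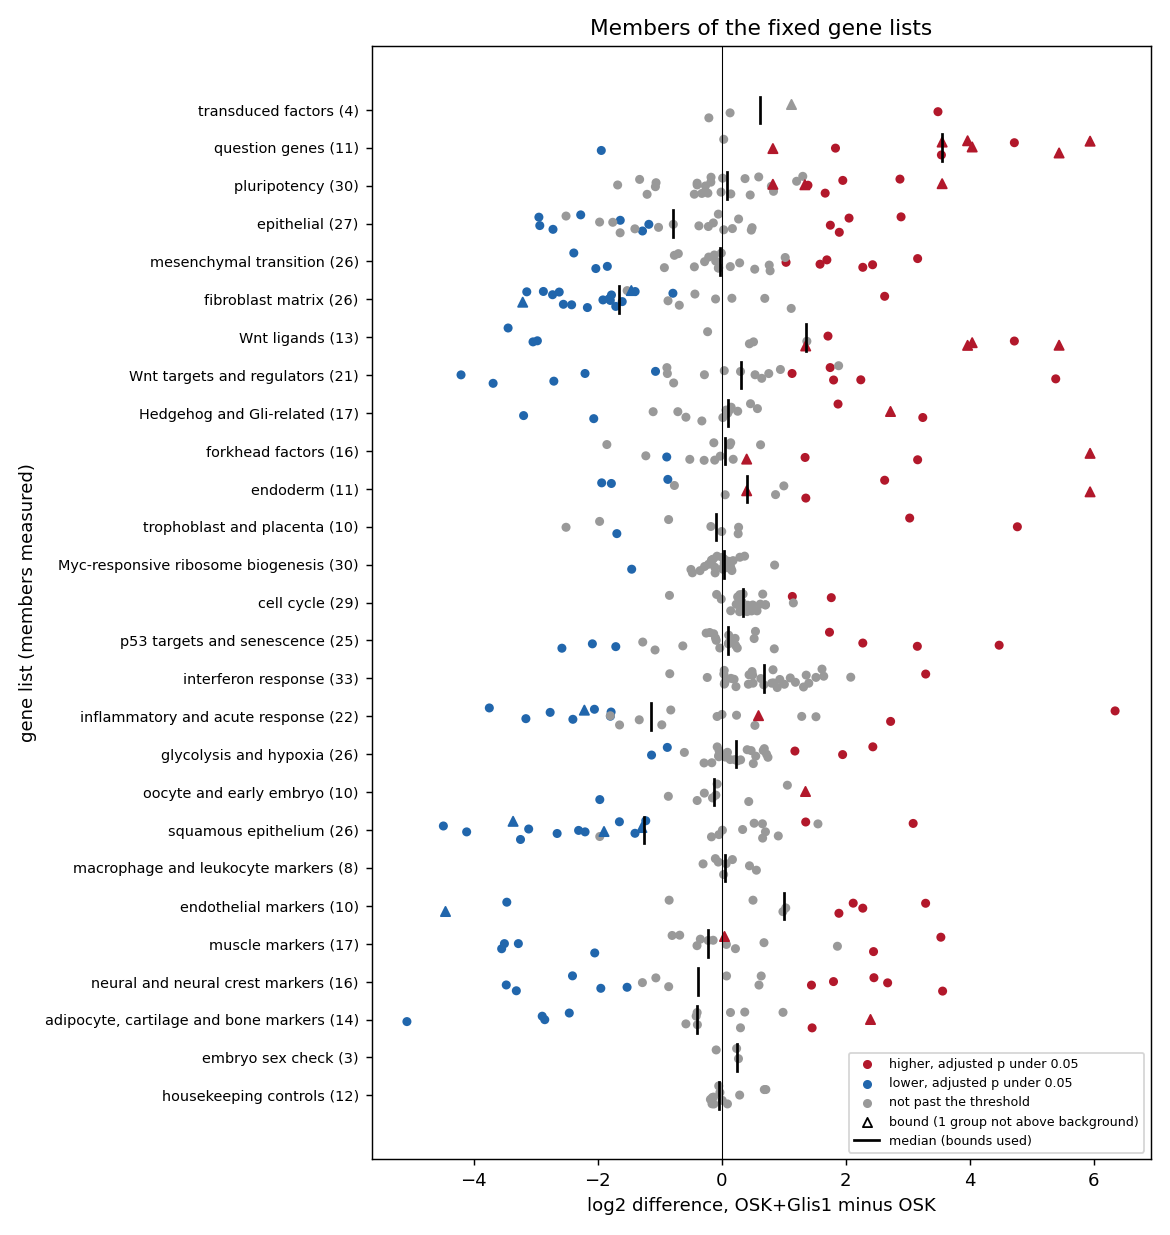
Log2 difference, OSK+Glis1 minus OSK (x axis), of each measured member of the 27 fixed lists (y axis, members measured in brackets). Colour marks genes higher (red) or lower (blue) at a limma adjusted p under 0.05, triangles are bounds for genes not well above background in 1 group, and black bars are medians with these bounds. The fibroblast matrix median lies at -1.66 and the housekeeping median at -0.04.

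Wnt pathway genes moved in both directions. Among 13 measured ligands 6 were higher and 3 lower (7 and 3 adjusted over the list alone), with a median of 1.37, or 1.35 with bounds, and a camera adjusted p of 0.122. Without OSK replicate 1 the count higher was 3. The median was 1.87 without OSK+Glis1 replicate 2, and the direction was downwards over genes well above background on all 4 arrays (camera adjusted p = 0.953). Beside the ligands named above, Wnt2 fell 10.9-fold (log2 difference -3.44 ± 0.24 SE, limma adjusted p = 0.00307). Of 21 Wnt targets and regulators 5 were higher and 5 lower (9 and 7 adjusted over the list alone; median 0.30, camera adjusted p = 0.869). Of these targets 3 were higher without OSK replicate 1, 2 without OSK replicate 2 and 3 without OSK+Glis1 replicate 1. The Wnt-responsive factor Sp5 rose 41.8-fold (5.39 ± 0.26 SE), while the antagonist Dkk2 fell 18.4-fold (-4.20 ± 0.21 SE), the transcription factor Lef1 12.9-fold (-3.69 ± 0.24 SE) and Dkk3 4.61-fold (-2.20 ± 0.17 SE).

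Hedgehog and Gli-related genes had 3 higher and 2 lower of 17 (3 and 5 adjusted over the list alone; median 0.10, camera adjusted p = 0.869). Indian hedgehog (Ihh) was at least 6.54-fold higher, and desert hedgehog (Dhh) fell 4.18-fold (log2 difference -2.06 ± 0.24 SE), a call lost without OSK replicate 2. Members lower numbered 1 without OSK replicate 1 and 0 without OSK replicate 2. Forkhead factors had 4 higher and 1 lower of 16 (4 and 1 adjusted over the list alone; median 0.05, camera adjusted p = 0.52), and besides Foxa2 the factor Foxc2 rose 8.94-fold (3.16 ± 0.31 SE). The lower forkhead call was lost without any 1 of the 4 arrays. Endoderm genes had 4 higher and 3 lower of 11 (4 and 4 adjusted over the list alone; median 0.87, or 0.40 with bounds, camera adjusted p = 0.65), and 2 were higher without OSK replicate 1 or without OSK+Glis1 replicate 1. The endocytic adaptor Dab2 fell 3.82-fold (-1.93 ± 0.18 SE) and the homeobox gene Hhex 3.43-fold (-1.78 ± 0.21 SE).

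Epithelial genes had 4 higher and 7 lower of 27 (4 and 12 adjusted over the list alone), with a median of -0.78 and a camera adjusted p of 0.0936. The counts were 2 higher and 1 lower without OSK replicate 1, 1 and 1 without OSK replicate 2, and 2 lower without OSK+Glis1 replicate 1. The camera adjusted p was 0.0261 with median centring and 0.0222 in the deposited values, both downwards, and the direction was also downwards without OSK+Glis1 replicate 2. The keratin Krt19 rose 7.42-fold (log2 difference 2.89 ± 0.16 SE), whereas the membrane protease St14 fell 7.71-fold (-2.95 ± 0.37 SE), a call lost without either OSK array in turn. Genes of mesenchymal transition had 6 higher and 3 lower of 26 (8 and 6 adjusted over the list alone), with a median of -0.03, a mean of 0.22 and a camera adjusted p of 0.869. The count higher was 3 without OSK replicate 1, without OSK replicate 2 or without OSK+Glis1 replicate 1, and 1 was lower without OSK replicate 2. The matrix protease Mmp2 fell 3.59-fold (-1.84 ± 0.18 SE), and the growth factor Tgfb1 rose 3.24-fold (1.70 ± 0.17 SE) while Tgfb2 fell 5.22-fold (-2.38 ± 0.27 SE), the last call being lost without either OSK array in turn.

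In cells labelled p53-null, the list of p53 targets and senescence genes had 4 higher and 3 lower of 25 members (5 and 4 adjusted over the list alone; median 0.11, camera adjusted p = 0.869). The apoptosis gene Pmaip1 rose 22.2-fold (log2 difference 4.47 ± 0.20 SE) and the stress gene Gadd45a 8.91-fold (3.15 ± 0.16 SE), while Igfbp3 fell 4.24-fold (-2.08 ± 0.19 SE). Myc-responsive ribosome biogenesis genes had 0 higher and 1 lower of 30 members (0 and 0 adjusted over the list alone; median 0.04, mean -0.03, camera adjusted p = 0.869). The lower member was the cyclin Ccnd2 (2.73-fold, log2 difference -1.45 ± 0.24 SE), which lost its call without either OSK array, without OSK+Glis1 replicate 1 or without a filter. Glycolysis and hypoxia genes had 3 higher and 2 lower of 26 (5 and 2 adjusted over the list alone; median 0.23, camera adjusted p = 0.207, and 0.011 without a filter). Neither lower call held without any 1 of the 4 arrays. The glucose transporter Slc2a3 rose 5.42-fold (2.44 ± 0.21 SE). The 12 housekeeping controls had 0 higher and 0 lower (0 and 0 adjusted over the list alone), a median of -0.04, a mean of 0.08 and a camera adjusted p of 0.869.

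Interferon response genes had a median difference of 0.68 over 33 members, with 1 higher and 0 lower (0 and 0 adjusted over the list alone) and a camera adjusted p of 0.0644. The chemokine Cxcl10 rose 9.78-fold (log2 difference 3.29 ± 0.68 SE, limma adjusted p = 0.0404), a call lost without either OSK array and without a filter. In the same list the 2 OSK+Glis1 arrays differed from each other by a median of 1.79, replicate 1 being higher for 32 genes. Without OSK+Glis1 replicate 2 the median was 1.51, and without OSK+Glis1 replicate 1 it was -0.23. The list's camera adjusted p was 0.00425 under normexp with flagged backgrounds replaced and 0.00108 without a filter, both upwards. Its members moved together, with an estimated correlation of 0.90, and with that correlation the camera adjusted p was 0.964.

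The genes with the largest differences were chosen by size among those past the threshold. Salivary gland protein genes Dcpp1 (at least 692.4-fold), Dcpp3 (at least 615.8-fold) and Dcpp2 (at least 190.3-fold) were higher, as were the neuronal calmodulin-binding gene Nrgn (at least 616.3-fold), Itih3 (at least 216.2-fold), Tspan18 (at least 131.3-fold) and Cilp (at least 59.4-fold). The Dcpp genes are near-identical copies whose probes may read each other's transcripts, so their separate values are uncertain. Measured on both OSK arrays, Cpsf4l rose 469.7-fold (log2 difference 8.88 ± 0.17 SE, limma adjusted p = 8e-04) and Sparcl1 rose 189-fold (7.56 ± 0.52 SE). The lens genes Grifin (337-fold, 8.40 ± 0.33 SE) and Cryba2 (329-fold, 8.36 ± 0.35 SE) were above background on 1 OSK array. On OSK replicate 2 they lay at -6.71 and -6.68, below the lowest well-above-background signal of -5.56. Their folds use these signals as they stand, so they may be too large beside the "at least" values. For the genes with bounds, values below background carry no order, and their place among the largest rests on the fitted differences.

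Among the largest falls, the glutathione transferase genes Gsta2 (at least 79.6-fold) and Gsta1 (89.2-fold, log2 difference -6.48 ± 0.58 SE) are paralogs and their values are uncertain for the same reason. Prokineticin 2 (Prok2) fell 76.0-fold (-6.25 ± 0.51 SE) with 1 OSK+Glis1 array above background, Mybpc2 fell 60.0-fold (-5.91 ± 0.42 SE), Slurp1 53.8-fold (-5.75 ± 0.61 SE) and Dmrtc2 41.4-fold (-5.37 ± 0.68 SE). Sptssb was at least 57.2-fold, arginase 1 (Arg1) at least 21.4-fold, Them5 at least 21.0-fold, Calb1 at least 16.1-fold, Npy2r at least 14.9-fold and Corin at least 10.4-fold lower. Dmrtc2 and Arg1 lost their calls without either OSK array in turn, and Calb1 lost its call in the deposited values.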

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

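The normexp version with flagged backgrounds replaced was chosen after seeing the data, and the other settings were planned. Of 102 named genes past the threshold, all 102 kept direction and threshold under quantile normalization, median centring, the mean of a gene's probes and the eBayes trend and robust settings, and 101 in the deposited values. 97 kept both under normexp with flagged backgrounds replaced and 92 without a filter. With all 4 arrays required above background, all 66 still tested did. None of the 102 reversed outside the planned normexp setting, where 10 did.

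Planned normexp gave 0 changed genes (0 higher, 0 lower), 0 named genes past the threshold, 617 genes higher and 2770 lower without overlap and at least 2-fold, and 12 gene lists. On OSK replicate 2, 6 spots had local backgrounds over their signal, up to 52390 against an array median of 31, and its fitted background mean was -662.8. With flagged backgrounds replaced that mean was -6.78, and 2849 genes changed, 2139 of them shared with the 2726 and all in the same direction. Under planned normexp these genes, among others, reversed in sign, none of them past the threshold there: Sox2 (-0.97), Lin28a (-0.94), Dppa3 (-0.88), Ihh (-0.34), Ptch1 (-0.59), Foxa3 (-1.18), Car9 (-0.26), Zar1 (-0.99), Cd14 (-0.24), Cd74 (-0.62), Laptm5 (-0.88), Esam (-0.47), Dcx (-0.38), Pax6 (-0.79), Kdm5d (-0.63), Ddx3y (0.11) and Tbp (-0.20). Lists reversed there too, with adjusted p of 0.352 for Wnt ligands and Hedgehog, 0.296 for Wnt targets, 0.6997 for endoderm, 0.00293 for Myc-responsive ribosome biogenesis, 0.192 for leukocytes and 0.964 for endothelium.

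With flagged backgrounds replaced, 1669 genes had no overlap and at least 2-fold (680 higher, 989 lower), Laptm5 reversed (-0.0558), and the Hedgehog and ribosome lists reversed (both 0.902). The added offset of 50 shrinks folds of dim genes by construction. Without a filter 1504 of 32172 genes changed (554 higher, 950 lower), 3054 were lower without overlap, and lists for ribosome biogenesis (0.512), leukocytes (0.643) and neural genes (0.608) reversed. Over genes above background on all 4 arrays 3 lists passed, and Wnt ligands (0.953), Wnt targets (0.978), Hedgehog (0.632) and endoderm (0.815) reversed. These settings test other genes. Ddx3y reversed with median centring (0.0486) and in the deposited values (0.0638). Wnt targets reversed in both (0.916 and 0.927), ribosome biogenesis in the deposited values (0.998) and housekeeping genes under quantile normalization (0.938). The cause was not tested.

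At an adjusted p of 0.1, 4092 genes passed (1883 higher). At 3-fold 1786 had no overlap (706 higher, 1080 lower). An estimated correlation left 0 lists, directional fry 2 and mixed fry 21, and under directional fry Wnt targets (0.276) and trophoblast genes (0.498) reversed.

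Leaving out 1 array gave 1219 to 1879 changed genes (449 to 786 higher, 664 to 1093 lower), 78 to 101 named genes past the threshold and 2 to 7 lists, the lone array of a group being assumed to vary like the other group. Fewer arrays lower the count by construction. Reversed genes lay between these bounds: Cdh1 -0.164 to 0.229, Ddx3y -0.320 to 0.143, Klf4 -0.246 to 0.517, Sox2 -0.0164 to 2.25, Glis1 -0.434 to 0.0199 and Laptm5 -0.105 to 0.451. Lists that reversed had adjusted p of 0.781 to 0.968 for Hedgehog, 0.34 to 0.937 for trophoblast, 0.622 to 0.968 for leukocytes, 0.249 to 0.728 for ribosome biogenesis, 0.759 to 0.884 for p53 targets, 0.234 to 0.884 for mesenchymal transition, 6.5e-13 to 0.585 for interferon and 0.478 to 0.95 for oocyte genes.

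With the replicate number as a block, 2654 genes changed (1111 higher, 1543 lower), and 7 lists passed, among them the epithelial (0.0436) and interferon (0.00221) lists. Equal numbers also share a number in the names of the deposited tables, of unstated meaning, and lie side by side on the slide. The labels say nothing of a shared batch, and 2 pairs are too few to show pairing from the data, so the numbers were not taken to pair the arrays. The deviations of same-numbered arrays correlated at 0.0094 across genes. Slide and scan as a block could not be fitted, as all arrays share both. Signal over background limits the dimmest genes, for which 212 rises and 251 falls have only a bound.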

Other observations

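The tests of symbol families and of technical explanations were chosen after the results were seen, while the lists of other cell types were fixed beforehand.

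Other gene groups also held members that moved. Of 10 tested genes grouped by the symbol stem Ly, 6 were lower (60%, against 9.14% of other genes; one-sided Fisher's exact p = 8.99e-05, adjusted p = 0.018 over 316 tests of 158 symbol families). They were Ly6c1 (log2 difference -3.85 ± 0.28 SE), Ly6h (-3.24 ± 0.20 SE), Ly6i, Ly6f, Ly6c2 and Ly6a, which code for small surface proteins. Several are close paralogs, so shared signal leaves their separate values uncertain. Fisher's test takes genes as independent, so with shared signal its p may be too small. Over 13 measured genes with symbols beginning with Ly6, 6 were lower, and the count was 2 without OSK replicate 1, 2 without OSK replicate 2, 3 without OSK+Glis1 replicate 1 (with 1 higher) and 2 of 16 without a filter. Their median was -1.12 and stayed below 0 in these settings and under the scalings tried. The other family past the threshold was Wnt, with 6 of 13 higher (46.2%, against 6.8%; one-sided Fisher's exact p = 0.000114, adjusted p = 0.018). Of these 6, 4 were not well above background in OSK and entered the test through the OSK+Glis1 arrays. Over genes well above background on all 4 arrays, 2 of 9 Wnt genes were higher and 3 lower, and without OSK replicate 1 the count higher was 3. The Wnt median was 1.37, fell to 0.45 over those 9 genes or without a filter and to 0.32 under normexp with flagged backgrounds replaced, and turned to -0.69 under planned normexp.

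Among the fixed lists of other cell types, endothelial markers had 4 higher and 2 lower of 10 (6 and 3 adjusted over the list alone; median 1.01, camera adjusted p = 0.322, and 0.04 without a filter), and 2 were higher without OSK replicate 1. The adhesion gene Esam rose 4.35-fold (log2 difference 2.12 ± 0.21 SE) and Egfl7 rose 3.71-fold (1.89 ± 0.21 SE), while claudin 5 (Cldn5) fell 11.0-fold (-3.46 ± 0.43 SE). Muscle markers had 3 higher and 4 lower of 17 (4 and 4 adjusted over the list alone; median -0.22, camera adjusted p = 0.38), and cardiac troponin T (Tnnt2) fell 9.70-fold (-3.28 ± 0.17 SE). Only 1 muscle marker was higher without either OSK array in turn or without OSK+Glis1 replicate 1. Neural markers had 5 higher and 5 lower of 16 (6 and 7 adjusted over the list alone; median -0.39, camera adjusted p = 0.869), and the growth cone gene Gap43 fell 9.93-fold (-3.31 ± 0.18 SE), while the RNA-binding protein gene Elavl3 rose 11.8-fold (3.56 ± 0.33 SE), a call lost without OSK replicate 2. Of the neural markers 2 were lower without OSK replicate 1, 3 were lower and 3 higher without OSK replicate 2, and 3 were lower without OSK+Glis1 replicate 1. Adipocyte, cartilage and bone markers had 2 higher and 4 lower of 14 (2 and 5 adjusted over the list alone; median -0.39, camera adjusted p = 0.296), and the fatty acid binding protein Fabp4 fell 5.49-fold (-2.46 ± 0.17 SE), while 1 was higher without OSK replicate 2 or without OSK+Glis1 replicate 1. Trophoblast genes had 2 higher and 1 lower of 10 (2 and 3 adjusted over the list alone; median -0.09, mean 0.11, camera adjusted p = 0.929), and Tfap2c rose 27.2-fold (4.77 ± 0.32 SE). Of the trophoblast genes 3 were lower without OSK replicate 2 and 1 was higher without OSK+Glis1 replicate 2. Oocyte genes had 1 higher and 1 lower of 10 (1 and 1 adjusted over the list alone; median -0.12, mean 0.05, camera adjusted p = 0.869), with 0 higher and 0 lower without either OSK array in turn, 0 lower without OSK+Glis1 replicate 1 and 2 higher without OSK+Glis1 replicate 2. Leukocyte markers (8 measured, median 0.05, camera adjusted p = 0.869) and Y-linked or Xist genes (3 measured, median 0.24, camera adjusted p = 0.839) had 0 higher and 0 lower, over all genes and adjusted over the list alone.

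The Glis1 probe was not higher in the arrays labelled OSK+Glis1. A swap of 1 array of each group is argued against, since the lowest correlation within a group exceeded the highest between groups by 0.0423. Whether the array's probes do not read the retroviral copies stays open: on the 2 OSK arrays the Pou5f1, Sox2 and Klf4 probes were well above background in 3 of 6 readings, Sox2 in 0, Pou5f1 in 1 and Klf4 in 2. The cells' own transcripts and the amount delivered were not measured apart. If the Glis1 probe reads the retroviral copy, a swap of both whole groups predicts a higher signal in the arrays labelled OSK. The difference was -0.21 ± 0.22 SE (limma adjusted p = 0.598), so such a rise was not shown. If the probe does not read that copy, its signal cannot show a swap, which then stays open. A mix-up outside the series stays open too.

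Interferon response genes differed between the 2 OSK+Glis1 arrays, by a median of 1.79 with replicate 1 higher for 32 of 33 genes, such as Ifi44 (3.42) and Usp18 (2.56). In the OSK arrays the same list differed by a median of 0.42. A scaling factor per array is argued against, since it moves all genes alike, while the list's median lay 1.88 above that of the housekeeping genes, more than their median absolute deviations of 0.51 and 0.05 together. Leukocyte RNA in replicate 1 stays open, because the 8 leukocyte markers were dim and differed by a median of 0.1665. No biological explanation was tested, as both arrays carry the same label. Other lists differed less between these 2 arrays, in either direction. Replicate 1 was higher by a median of 0.59 for inflammatory genes (20 of 22) and 0.58 for fibroblast matrix genes (22 of 26). For mesenchymal transition genes it was higher by 0.33 (24 of 26). Epithelial genes had a median of -0.53, with 4 of 27 higher in replicate 1.

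Fibroblast matrix genes were lower in OSK+Glis1 by a median of -1.74. A scaling factor per array is argued against, since the list's median lay below the housekeeping median with a gap of -1.70, more than their median absolute deviations of 0.92 and 0.12 together. A smaller share of fibroblasts stays open, as the whole cause or as part of it. The 8 abundant mesenchymal genes outside the list had a median of -0.164. Of these, 6 had negative differences, from Sparc (-0.70) and Acta2 (-0.44) to Tgfbr2 (-0.05), and Fn1 (0.78) and Tagln (0.77) had positive ones. These genes cannot decide the question, because whether other cells in the cultures express them was not measured. A change in matrix gene expression that goes with Glis1 stays a hypothesis, found and tested on the same 4 arrays.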
